A study of Mus musculus with 4 samples.

How the data were processed

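Gene expression was measured by RNA sequencing in the sublingual gland, a mucous salivary gland, of female mice on a C57BL/6J background with both copies of Nkx2-3 knocked out. Per the labels' protocols, glands were flash frozen, RNA was extracted with Trizol, and libraries were made with the Illumina TruSeq RNA kit from 1 ug of total RNA. The 4 libraries fall into 2 ages, with 2 libraries (replicates 1 and 2) at 8 weeks and 2 libraries (replicates 3 and 4) at 32 weeks. Per the submitters' processing notes, the authors aligned reads with STAR to the mouse build mm9. The STAR version, the counting tool, the gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The deposited values are whole-number read counts per gene symbol with no normalization, for 24411 symbols in 1 column per library. Because the counting is not described, counts of overlapping genes and of near-identical gene copies are uncertain, and a gene cannot be told from an antisense partner.

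Everything after the counts was computed here in R 4.3.3. The main test was edgeR 4.0.16's quasi-likelihood test on the counts as deposited, with TMM factors, the default low-count filter by age, and Benjamini-Hochberg adjustment over the 12810 genes kept, at an adjusted p threshold of 0.05. Age was the only term. Log2 fold changes are 32 weeks over 8 weeks, with 95% intervals from the same model, and CPM values are scaled by TMM. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these libraries only, which may be technical. With 2 libraries against 2 there are 3 splits of the libraries, and the smallest exact permutation p for a single value is 0.333, so no permutation test can reach the threshold.

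A set of 30 gene lists (cell types, secretory products, pathways and control genes) was tested with limma 3.58.1's camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists with at least 3 tested members. Camera with an estimated correlation and the rotation test fry were run beside it. The lists, the design, the first set of alternatives and the rule for named genes were fixed before the data were examined. The rule named the 10 largest rises and the 10 largest falls past the threshold with a mean of at least 10 CPM and no overlap between the ages, leaving out symbols that are only gene-model names. It also named up to 3 members past the threshold in each called list and up to 1 in each other list, a set of control genes (Nkx2-3, Madcam1, Muc19, Muc5b, Smgc, Bpifa2, Dcpp1, Aqp5, Xist, Ddx3y, Uty, Eif2s3y and Kdm5d), and the 5 genes with the most counts (Dcpp3, Smgc, Dcpp2, Dcpp1 and Spt1). No gene met its first or second part, so every gene named apart from the control genes and the 5 most abundant was chosen after its values were seen.

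Alternatives were RLE size factors, total counts only, the 10 most abundant genes left out, no low-count filter, a filter of at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, and each library left out in turn. A clock-gene score and 1 surrogate variable (sva 3.50.0) as covariates were added after seeing the data. The scripts were tested on simulated data with known fold changes. Gene positions come from the GENCODE vM1 annotation on NCBIM37, the assembly that mm9 names. Of the symbols, 20836 matched that annotation by name, 1392 through an older or newer symbol, and 2183 had no match. Transcript GC content and length came from the longest protein-coding transcript of each matched gene. The check of these 2 properties was run first with symbols matched by name alone and again after the older and newer symbols had been added. The runs gave different shares of calls kept, and both are reported. The size of the fold changes was then compared before and after as well. Figures were drawn with matplotlib.

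Depth was 12925869 and 14265485 counts in the 8-week libraries and 16484772 and 16111122 counts in the 32-week libraries. A count of 0 allows up to 3 counts, which is 0.174 to 0.221 TMM-scaled CPM by library, and such limits cover counting error only. No wild-type library was analysed here, so no value can be set against a gland with intact Nkx2-3.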

Results

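RNA sequencing counts were examined for the sublingual gland of female Nkx2-3 knockout mice at 8 weeks (n = 2 libraries) and 32 weeks (n = 2 libraries). The series text speaks of 4 replicates, and the labels place 2 libraries at each age. Total counts were 12925869 and 14265485 in 8-week replicates 1 and 2, and 16484772 and 16111122 in 32-week replicates 3 and 4. Between 16139 and 16484 genes had at least 1 count in a library. The comparison the design allows is that of the 2 ages within the knockout.

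Nkx2-3, the deleted homeobox gene (NCBIM37 chromosome 19, 43686815 to 43690381, plus strand), had 31 and 28 counts in the 8-week libraries and 21 and 29 counts in the 32-week libraries, or 1.45 to 2.29 CPM. Which part of the gene was removed is not given in the sources used here, and reads from a remaining part would be counted. Madcam1, a vascular adhesion molecule (chromosome 10, 79127319 to 79131281), had 0 counts in all 4 libraries, which allows at most 0.221 CPM. The Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d also had 0 counts in each library, and Xist, expressed from the inactive X chromosome, stood at 247 and 105 CPM at 8 weeks and 124 and 159 CPM at 32 weeks. Muc5b, a gel-forming mucin, had 0 or 1 counts in each library.

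The libraries were dominated by secretory transcripts. The 5 most abundant genes, Dcpp3, Smgc, Dcpp2, Dcpp1 and Spt1, took 37.0% and 39.1% of the counts in 8-week replicates 1 and 2 and 40.7% and 35.4% in 32-week replicates 3 and 4. Dcpp3, a demilune secretory protein, stood at 81960 and 178600 CPM at 8 weeks and at 249000 and 90260 CPM at 32 weeks (log2 fold change 0.38, SE 0.82, edgeR adjusted p = 0.999). Smgc stood at 142100 and 73280 CPM at 8 weeks and at 41970 and 125900 CPM at 32 weeks. Spt1 stood at 65020 and 3654 CPM at 8 weeks and at 3102 and 36100 CPM at 32 weeks. Bpifa2, a salivary protein of the same abundance class, had 15260 and 37650 CPM at 8 weeks and 42620 and 13010 CPM at 32 weeks. For Dcpp3, Smgc, Dcpp2, Dcpp1, Spt1 and Bpifa2 the spread within an age exceeded the difference between the ages. Muc19, the main gel-forming mucin of this gland, had 12020 and 13870 CPM at 8 weeks and 20280 and 16720 CPM at 32 weeks (log2 fold change 0.52, SE 0.44, 95% interval -0.52 to 1.55, edgeR adjusted p = 0.999). Muc19 (chromosome 15, 91668757 to 91766819) and Smgc (91668696 to 91691869) share 23113 bases on the same strand, and the Dcpp genes are near-identical copies, so the division of reads among them is uncertain. Aqp5, the acinar water channel, had 540 and 242 CPM at 8 weeks and 602 and 467 CPM at 32 weeks.

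**Figure D1:**
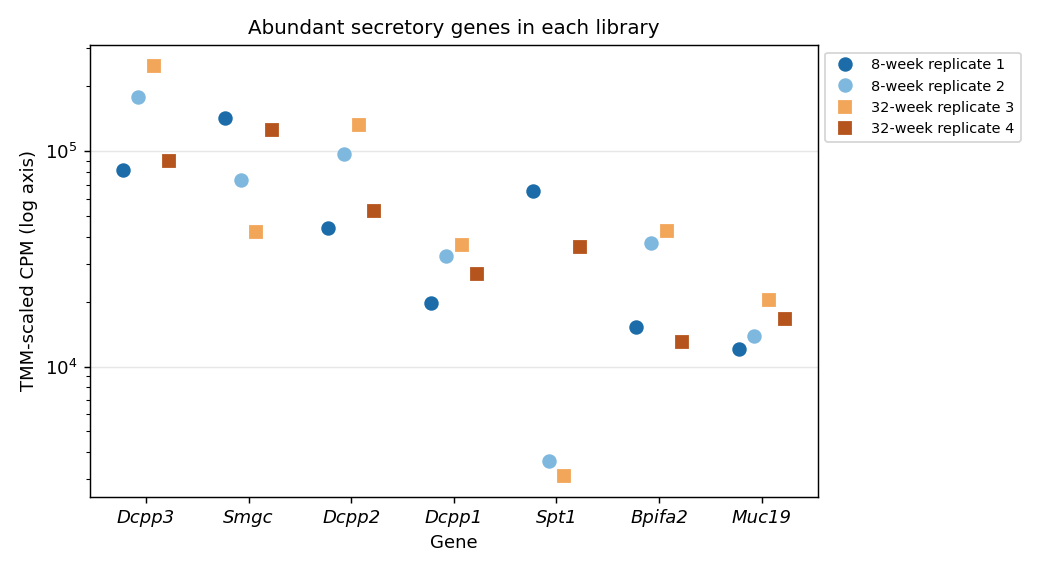
TMM-scaled CPM on a log axis for 7 abundant secretory genes, with 1 point per library (circles for 8 weeks, squares for 32 weeks). For Spt1, 8-week replicate 1 (65020 CPM) and 32-week replicate 4 (36100 CPM) lie far above 8-week replicate 2 (3654 CPM) and 32-week replicate 3 (3102 CPM).

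The pair of libraries most alike crossed the labelled ages. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.958 between the 8-week libraries and 0.979 between the 32-week libraries, 0.984 between 8-week replicate 1 and 32-week replicate 4, and 0.970 between 8-week replicate 2 and 32-week replicate 3, which is below that between the 32-week libraries. No library repeated another within sampling noise. Chi-square per degree of freedom was 225 between the 8-week libraries and 255 between the 32-week libraries, against 22.4 between 8-week replicate 1 and 32-week replicate 4 and 52.8 between 8-week replicate 2 and 32-week replicate 3. These values are set against counting noise only and do not show whether the libraries came from separate animals. Rn45s, the ribosomal RNA precursor, took 3.69% and 1.40% of counts at 8 weeks and 2.24% and 3.38% at 32 weeks.

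No gene passed the main test of the age comparison. With edgeR, 0 of 12810 genes reached an adjusted p of 0.05, the smallest adjusted p was 0.784, and 174 genes had an unadjusted p under 0.05 where 640.5 would be expected by chance. DESeq2, run on 18104 genes without that low-count filter, called 3 genes, all lower at 32 weeks. It had 89 genes at an unadjusted p under 0.05 where 905.2 would be expected by chance. On the 12810 genes limma-voom called 0, with 177. The 3 genes, which were chosen after their values were seen, were Lrrk2, Klk1b22 and Smr3a. Lrrk2, a kinase gene that lies just upstream of Smgc and Muc19 on chromosome 15 (91503606 to 91646551), had 17.5 and 15.7 CPM at 8 weeks and 3.87 and 5.24 CPM at 32 weeks (log2 fold change -1.86, SE 0.24; DESeq2 adjusted p = 0.00207, edgeR adjusted p = 0.784). Klk1b22, a tissue kallikrein with close paralogs, had 11.6 and 8.42 CPM at 8 weeks and 2.35 and 2.21 CPM at 32 weeks (log2 fold change -2.13, SE 0.29; DESeq2 adjusted p = 0.0024, edgeR adjusted p = 0.784). In edgeR, Klk1b22 passed with total counts only (adjusted p = 7.2e-05) and with no low-count filter (adjusted p = 0.00114). Lrrk2 passed with the same settings (adjusted p = 4.16e-05 and 0.00114). Both settings also called Amy1, which was high in 8-week replicate 1 alone (adjusted p = 1.78e-40 and 0.00381). With 1 library left out, the log2 fold change ranged from -2.34 to -1.88 for Klk1b22 and from -2.095 to -1.66 for Lrrk2. With covariates added after seeing the data, both genes passed with the clock score (Klk1b22 adjusted p = 0.0309, Lrrk2 adjusted p = 0.0256) and with the surrogate variable. Both covariates were computed from these same counts, the surrogate variable with age kept in the model. They also leave fewer degrees of freedom, so these p-values may be too small. Smr3a had 674 counts in 8-week replicate 1 and 0 in each other library, and the low-count filter kept it out of the main edgeR test. The median 95% interval of a log2 fold change reached 0.61 to either side. In simulated comparisons of 32 with 8 weeks, with counts drawn for 12810 genes and 200 of them changed, edgeR recovered 11.3% of 2-fold changes, 93.2% of 4-fold changes and 99.3% of 8-fold changes. Beside a mean of 22.7 genes recovered at 2-fold it made 6.33 false calls, beside 186 at 4-fold 22, and beside 199 at 8-fold 19.7, so its false calls exceeded the nominal share. DESeq2 recovered 25% of 2-fold changes with 11.7 false calls beside 50. The simulation drew each gene independently, changed only genes of at least 1 CPM and held no division of the libraries that crosses the ages. These shares therefore do not say how many real age changes of such sizes were missed. The count rested on single libraries, with 285 genes called by edgeR without 8-week replicate 1, 6 without 8-week replicate 2, 11 without 32-week replicate 3 and 17 without 32-week replicate 4. Both libraries of an age lay above both of the other in 28.6% of genes, against 33.3% by chance.

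The list of secretory proteins known from the submandibular and parotid glands leaned lower at 32 weeks. Of 23 tested members, 19 had a negative fold change, and the median log2 fold change was -0.93. Most of the 19 were Klk1 and Klk1b genes, close paralogs whose counts are uncertain. The 4 positive members were Scgb1b27, Scgb2b26, Scgb2b27 and Dcpp1. The list passed camera's test with a preset correlation (adjusted p = 3.14e-21). It did not pass with an estimated correlation (adjusted p = 0.868) or with fry (adjusted p = 0.927). With the preset correlation it also passed when 8-week replicate 1 and 32-week replicate 4 were set against the rest (adjusted p = 0.0322). With edgeR no member passed over all genes, and 6 passed when adjusted over the list alone: Prol1, Klk1b4, Klk1b5, Klk1b22, Klk1b24 and Amy1. DESeq2 called Klk1b22 and Smr3a over all genes (adjusted p = 0.0024 for each), and Smr3a is not among the 23 members tested with edgeR. Prol1, a salivary mucin-type protein, had 196 and 203 CPM at 8 weeks and 10.02 and 0.407 CPM at 32 weeks (log2 fold change -5.28, SE 1.02, edgeR adjusted p = 0.999). Prol1 passed in edgeR with total counts only (adjusted p = 5.17e-41) and with no low-count filter (adjusted p = 2.51e-05). The same settings also called Amy1 (adjusted p = 1.78e-40 and 0.00381) and Dnase1 (adjusted p = 6.78e-16 and 0.0135), each high in 8-week replicate 1 alone. Calls under these settings therefore need not rest on both libraries of an age. The log2 fold change of Prol1 was -8.90 without 32-week replicate 3 and -4.31 without 32-week replicate 4. Klk1b5 had 5.76 and 9.39 CPM at 8 weeks and 2.56 and 2.44 CPM at 32 weeks. Amy1, salivary amylase, was high in 8-week replicate 1 alone, with 152 CPM against 2.002 CPM in 8-week replicate 2 and 2.005 and 1.63 CPM at 32 weeks. Klk1, an abundant kallikrein, had 2005 and 4327 CPM at 8 weeks and 2175 and 1309 CPM at 32 weeks. Without 8-week replicate 2 the list's median was -0.32.

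**Figure D2:**
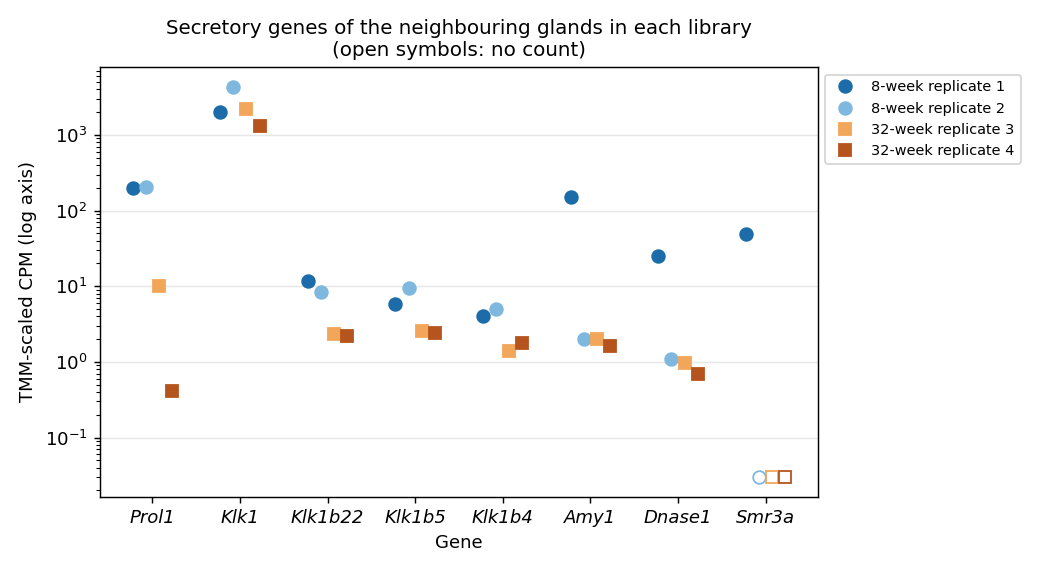
TMM-scaled CPM on a log axis for secretory genes of the neighbouring glands, with 1 point per library (circles for 8 weeks, squares for 32 weeks) and open symbols where a library had no count. Prol1 is near 200 CPM in both 8-week libraries (196 and 203), and Amy1, Dnase1 and Smr3a are high in 8-week replicate 1 alone.

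The B cell and plasma cell, mucous acinar and ribosomal protein lists were lost without 8-week replicate 2. All 8 tested B cell and plasma cell genes had positive fold changes (median log2 0.45, camera adjusted p = 0.00183 with a preset correlation, adjusted p = 0.868 with an estimated correlation), and none passed singly. Relative to each gene's mean log2 CPM, this list's median was lowest in 8-week replicate 2 (-1.45). The T cell and NK cell (-0.57), macrophage and dendritic cell (-0.46), mast cell and granulocyte (-0.71) and MHC class II (-0.42) lists were lowest there too. The type I and gamma interferon lists were not (0.17 and 0.11). In 32-week replicate 3 the T cell and NK cell (-0.4) and mast cell and granulocyte (-0.36) lists were also low. The macrophage and dendritic cell (-0.08) and MHC class II (-0.05) lists were less so there, and the B cell and plasma cell list was not (0.2). Jchain, the joining chain of secreted antibodies, had 920 and 73.7 CPM at 8 weeks and 512 and 799 CPM at 32 weeks. The mucous acinar list had 10 of 12 tested members positive (median 0.28, adjusted p = 0.0185 with a preset and adjusted p = 0.868 with an estimated correlation). Agr2, a mucin-folding disulfide isomerase, had 57.2 and 5.59 CPM at 8 weeks and 49.6 and 49.7 CPM at 32 weeks. Cytosolic ribosomal protein genes had 71 of 74 members positive (median 0.24, adjusted p = 4.17e-10 with a preset and adjusted p = 0.868 with an estimated correlation). Without 8-week replicate 2 the median was -0.31 for the B cell and plasma cell list, -0.05 for the mucous acinar list and 0.03 for ribosomal proteins, and none of the 3 lists passed. Without 8-week replicate 1 the medians were 2.17, 0.48 and 0.52 in that order, and that of the B cell and plasma cell list was 0.69 without 32-week replicate 3 and 0.18 without 32-week replicate 4. With no low-count filter the B cell and plasma cell list (20 members, median 0.17, adjusted p = 0.85) and the mucous acinar list (median 0.27, adjusted p = 0.0503) did not pass. The B cell and plasma cell median was 0.76 with the clock score and 0.96 with the surrogate variable as covariate, and the ribosomal protein median was 0.16 with total counts only.

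The endothelial, extracellular matrix and myoepithelial lists had small positive medians. Endothelial genes were positive in 16 of 17 members (median 0.34, adjusted p = 0.00183), extracellular matrix genes in 24 of 32 (median 0.16, adjusted p = 0.00474), and myoepithelial and basal cell genes in 12 of 14 (median 0.25, adjusted p = 0.0215), each with a preset correlation and each with adjusted p = 0.868 with an estimated correlation. Col4a1, a basement membrane collagen, had 31.3 and 29.8 CPM at 8 weeks and 54.9 and 38.9 CPM at 32 weeks (log2 fold change 0.62, SE 0.23, edgeR adjusted p = 0.999; 0.36 without 32-week replicate 3 and 0.85 without 32-week replicate 4). Acta2, the contractile actin of myoepithelium and vessel walls, had 207 and 275 CPM at 8 weeks and 288 and 291 CPM at 32 weeks. None of the 3 lists passed without 8-week replicate 1 (adjusted p = 0.359, 0.359 and 0.535 in that order), where the medians were 0.31, 0.14 and 0.12, so that of the myoepithelial list alone was much smaller. The matrix list was also lost without 32-week replicate 3 (median 0.05, adjusted p = 0.454), and the myoepithelial list without 32-week replicate 4 (median 0.06, adjusted p = 0.735). Without 32-week replicate 3 the endothelial median was 0.22 and the myoepithelial median 0.38. With no low-count filter the myoepithelial list did not pass (median 0.23, adjusted p = 0.0703), and with total counts only the matrix median was 0.05 and the endothelial median 0.21.

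Duct, proliferation and adipocyte lists were lower at 32 weeks under the preset correlation. Duct genes were negative in 14 of 17 members (median -0.19, adjusted p = 0.00207), with Fxyd2, a sodium pump subunit, at 102 and 365 CPM at 8 weeks and 116 and 112 CPM at 32 weeks. Proliferation genes were negative in 25 of 29 members (median -0.27, adjusted p = 0.00207), with Mki67 at 2.73 and 5.11 CPM at 8 weeks and 4.56 and 1.16 CPM at 32 weeks. Adipocyte genes were negative in 7 of 10 members (median -0.36, adjusted p = 0.0185), with Car3 at 20.2 and 2.76 CPM at 8 weeks and 0.0691 and 2.97 CPM at 32 weeks. Each of the 3 lists had adjusted p = 0.868 with an estimated correlation. Without 8-week replicate 2 the duct median was 0.12 and the proliferation median 0.17, and neither passed. The proliferation list was also lost without 32-week replicate 4 (median -0.09), where its test pointed upward, and the adipocyte list without 8-week replicate 1 (median -0.14, adjusted p = 0.457). The adipocyte median was -0.24 without 8-week replicate 2, -0.20 without 32-week replicate 3, -0.59 with no low-count filter and -0.15 with the CPM filter, under which the proliferation median was -0.16. Without 8-week replicate 1, 32-week replicate 3 and 32-week replicate 4 in turn, the duct median was -0.95, -0.51 and -0.36, and the proliferation median was -0.51 and -0.74 without the first 2 of these.

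**Figure D3:**
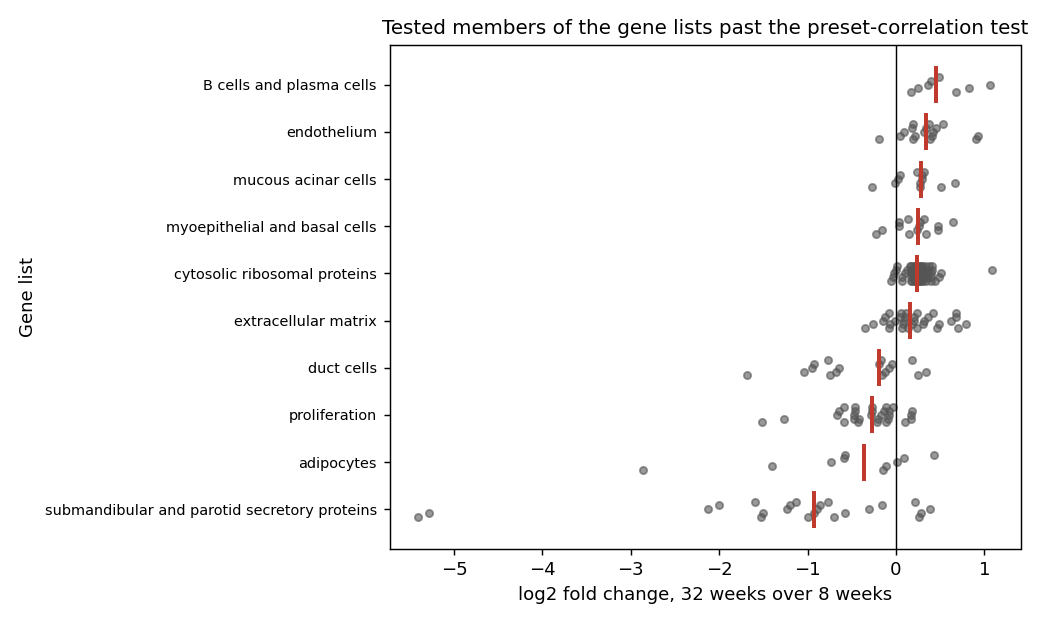
Log2 fold changes (32 weeks over 8 weeks) of the tested members of the 10 gene lists that passed camera with a preset correlation, 1 point per gene, with the median as a vertical bar. The submandibular and parotid list has the lowest median (-0.93) and the B cell and plasma cell list the highest (0.45), and none of the 10 lists passed with an estimated correlation.

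List calls with the preset correlation were not particular to the labelled ages. Of the other divisions of the 4 libraries into pairs, that of 8-week replicate 1 and 32-week replicate 4 from the rest called 17 lists. The remaining one called 5, against 10 by age, and the ribosomal protein, duct, and B cell and plasma cell lists passed in each. With an estimated correlation no list passed along either of the other divisions (smallest adjusted p = 0.475 and 0.905 in that order). The other 18 tested lists did not pass the age comparison with either correlation. Median log2 fold changes were 0.13 for serous and demilune cells, -0.06 for acinar fluid secretion and -0.02 for salivary transcription factors. Among immune lists they were 0.12 for T cells and NK cells, 0.08 for macrophages and dendritic cells, 0.45 for mast cells and granulocytes, 0.10 for MHC class II antigen presentation, -0.09 for the type I interferon response, -0.05 for the interferon gamma response, 0.08 for lymphoid chemokines and high endothelial venules, and 0.25 for complement and acute phase genes. They were 0.09 for the unfolded protein response, 0.22 for senescence genes, 0.19 for skeletal muscle, 0.07 for Schwann cells and nerve, 0.11 for oxidative phosphorylation, -0.17 for the circadian clock (adjusted p = 0.112 with a preset correlation) and 0.06 for immediate early and dissection stress genes. The mean differed in sign from the median for serous and demilune cells (-0.21), acinar fluid secretion (0.01), salivary transcription factors (0.01), skeletal muscle (-0.06) and Schwann cells and nerve (-0.01). Red blood cell genes (2 tested) and sex-linked genes (1 tested) were too few for a list test.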

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

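The clock score and the surrogate variable were chosen as covariates after seeing the data, and the other alternatives were set before the data were examined. The count of 0 genes between the ages also held with RLE size factors, with the 10 most abundant genes left out, with the CPM filter and with limma-voom. It was 10 with total counts only, 7 with no low-count filter, 3 with DESeq2, 4 with the clock score and 48 with the surrogate variable, and 6 to 285 when 1 library was left out. The cause was not tested. The count of 10 gene lists became 0 with an estimated correlation and 0 with fry, and lay between 7 and 14 under the other alternatives run for lists, which do not include DESeq2 or limma-voom. The B cell and plasma cell, mucous acinar and myoepithelial lists were lost with no low-count filter (adjusted p = 0.85, 0.0503 and 0.0703). Total counts shifted the log2 fold changes of all genes by a median of -0.09. Bpifa2 changed sign with total counts only (-0.08 against 0.07). When 1 library was left out, the log2 fold change ranged from -1.36 to 0.23 for Smgc, from -1.01 to 0.87 for Bpifa2, from -0.029 to 0.69 for Dcpp1, from -0.41 to 1.09 for Dcpp2, from -0.52 to 1.06 for Dcpp3, from -3.47 to 2.42 for Spt1, from -0.009 to 1.15 for Aqp5, from -0.80 to 0.43 for Xist, from -0.20 to 3.15 for Agr2, from -0.48 to 3.15 for Jchain, from -8.90 to -4.31 for Prol1 and from 0.36 to 0.85 for Col4a1. List medians ranged from -0.053 to 0.48 (mucous acinar cells), from -0.95 to 0.12 (duct cells), from -0.31 to 2.17 (B cells and plasma cells), from -0.74 to 0.17 (proliferation), from -1.24 to -0.32 (submandibular and parotid secretory proteins), from 0.027 to 0.52 (ribosomal proteins), from 0.053 to 0.23 (extracellular matrix), from 0.06 to 0.38 (myoepithelial and basal cells), from 0.22 to 0.35 (endothelium) and from -0.53 to -0.14 (adipocytes). Such fits leave 1 library at an age, which is assumed to vary like the pair at the other age. The highest r between ages exceeded the highest r within an age by 0.0048 on the log2 scale and by 0.069 on the square-root scale. No paired analysis was possible because the ages share no replicate number. A gene with no count in a library may still be expressed there at up to 0.174 to 0.221 CPM, by library.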

Other observations

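The gene choices and the tests in this part came after the values were seen, apart from the age comparison, which was planned. Members of the circadian clock, proliferation, B cell and plasma cell, other immune cell and interferon lists were fixed beforehand. Their tests along divisions other than age were not. The test of Per-phase against Arntl-phase genes was also set afterwards. Genes of cholesterol synthesis had a shared order across the libraries that did not follow the labelled ages. Of 22 such genes, 21 (95.5%) were higher in both 8-week replicate 2 and 32-week replicate 3 than in both other libraries, against 20.0% of all genes and 16.7% by chance. Fdps, a farnesyl diphosphate synthase, had 25.02, 65.7, 81.9 and 16.9 CPM in replicates 1 to 4, and Hmgcs1, which makes HMG-CoA, had 19.6, 47.1, 53.6 and 14.4 CPM. Secretoglobin Scgb2b2 had the opposite order, with 278, 13.0, 23.2 and 161 CPM. Clock genes of opposite phase were ordered in opposite ways. Arntl had 9.59, 1.66, 1.80 and 12.4 CPM and Npas2 7.01, 1.45, 1.24 and 7.15 CPM in replicates 1 to 4, while Per3 had 22.4, 71.1, 47.6 and 15.9 CPM and Nr1d1 79.8, 146, 140 and 66.2 CPM.

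Of the 3 ways to divide the libraries into pairs, 1 sets 8-week replicate 1 and 32-week replicate 4 against 8-week replicate 2 and 32-week replicate 3. It called 58 genes with edgeR (114 with DESeq2, 1217 at an unadjusted p under 0.05). The division by labelled age called 0 (3 with DESeq2, 174) and the remaining division 0 (1 with DESeq2, 299). The counts point to a structure of the samples other than the labelled ages. After each library's trend with GC content and transcript length was removed, the median size of the called genes' log2 changes was 1.54 (1.54 before) with symbols matched by name alone, the run made first, and 1.55 (1.56 before) with older and newer symbols added (median SE 0.24 before and 0.23 after in both), 1 gene in each run fell by more than its SE, and the Per-phase minus Arntl-phase median difference was 3.54 (3.51 before), which argues against such a trend as the source of the changes. The number of calls, on which the bound was first set, does not settle it. In the first run 16 of 43 (37.2%) were kept, which met the bound set in favour of such a trend. In the other run 38 of 57 (66.7%) were kept, which met the bound set against it. The comparison of sizes was added after these counts. Calls ended because adjusted p rose, to at most 0.173 and 0.155, while the lost genes' median size went from 1.48 to 1.44 and from 1.30 to 1.27. Glands taken at different times of day are a candidate explanation. The median difference between 11 Per-phase and 4 Arntl-phase genes was 3.51 along the division with 58 calls, -0.28 along the age division and -0.20 along the remaining one. The value of 3.51 lies outside the middle 95% of 10000 random gene sets matched on expression (-0.46 to 0.44). The permutation p over gene sets was 1e-04, the smallest these draws can give. But random sets ignore the correlation among clock genes. The division was also singled out after the values were seen, and 10 of the 20 clock list genes were among its calls. The clock list, with both phases together, had camera adjusted p = 0.000236 with a preset and adjusted p = 0.476 with an estimated correlation along it. Clock genes were not alone. Along this division camera with a preset correlation also called the macrophage (median log2 -0.52), T cell (-0.8) and mast cell (-1.67) lists. These were lower in 8-week replicate 2 and 32-week replicate 3, and the type I interferon list, also called, was higher (0.35). Each had adjusted p = 0.475 with an estimated correlation. Rn45s took 3.69% and 3.38% of counts in replicates 1 and 4, and 1.40% and 2.24% in replicates 2 and 3. Tissue content and RNA quality were not tested. Harvest times are not given in the sources used here. An exchange of age labels in each group could give the same picture and stays open. Proliferation genes were higher (median log2 0.75) and B cell and plasma cell genes lower (median log2 -1) in 8-week replicate 2 and 32-week replicate 3. Camera gave adjusted p = 1.28e-08 and 1.21e-06 with a preset correlation but adjusted p = 0.475 and 0.476 with an estimated correlation. The test that was set asked both lists to pass with an estimated correlation, so it did not decide the question. No list passed in that way along any of the 3 divisions, so this test could hardly have decided it either way. The directions expected also depend on which libraries were exchanged. Prol1, Lrrk2 and Klk1b22 were lower in both 32-week libraries than in both 8-week libraries, the order the labels give. They were picked after their values were seen, so their order does not weigh against an exchange. Both libraries of an age lay above both of the other in 28.6% of tested genes, against 33.3% by chance.

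Amy1, Dnase1, Smr3a and Chia1 were higher at 8 weeks through a single library, with at least 22.5-fold more in 8-week replicate 1 than in any other library (against a floor of 3 counts where the others had fewer). Age stays open for them: 0 of them had 8-week replicate 2 more than 2-fold above both 32-week libraries, but they were picked for being high in 8-week replicate 1 alone, so this count decides nothing. Parotid or other neighbouring tissue in 8-week replicate 1 may be the source, which the 22.5-fold excess leaves open because no profile of that tissue was analysed here.

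Prol1 and Klk1b22 were instead higher in both 8-week libraries. Submandibular tissue in both may account for this, and so may age; these cannot be told apart, because Klk1, abundant in that gland, was at 0.922 of the higher 32-week library in the lower 8-week library, and its high level in each library would hide a small share.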
